A study of Mus musculus with 4 samples.

How the data were processed

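Group 2 innate lymphoid cells were sorted from mouse adipose tissue, total RNA was extracted with Trizol and libraries were made with a Smart mRNA-seq kit, per the labels' protocols. The gate used for sorting, the read length and the strandedness are not given in the sources used here. The genome build was mm10, per the submitters' processing notes, and the aligner, the counting program and the annotation are not given in the sources used here. The deposited table lists 10941 genes by symbol and Entrez number. The authors deposited an estimated count of reads per gene and library, of which 20.0% to 21.6% per library are not whole numbers, so each was rounded to a whole count for the tests below. The authors also deposited the results of their own DESeq2 comparison in that table, namely a log2 fold change, a p-value and a q-value per gene, per the file headers. A further 12 columns of per-sample normalised values were not used.

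Each gene was listed with a count above 0 in at least 1 library, 9825 genes had one in all 4 and 2 genes in a single library. No mitochondrially encoded gene was listed, so the share of mitochondrial transcripts was not analysed here. Entrez numbers of 10906 genes (99.7%) were found in the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, and gene positions come from it. Transcript lengths, taken as the longest annotated transcript of each gene, were available for 10640 genes (97.2%) from the GENCODE annotation of the same assembly.

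The library names put 2 libraries in each of 2 groups, called WT-named and KO-named here. In all 4 samples the title gives the opposite Rptor genotype from the library name. Directions are therefore stated between libraries by their names, as KO-named minus WT-named. The count columns are numbered 1 and 3 in each group whereas the labels number the libraries 1 and 2. The columns numbered 1 could be tied to a sample, and those numbered 3 only to a group. Libraries are called by the number of their column. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

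Totals were 18151495 and 17868383 counts in WT replicates 1 and 3, and 15258779 and 18856226 in KO replicates 1 and 3. A count of 0 in a library allows up to 0.138 to 0.224 CPM, counts scaled to a common library total, which is the level of 3 counts. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. The 95% intervals of the closing observations are over genes, by bootstrap or exact binomial, and not over libraries. Where a group held no read of a gene, the fold is a lower bound against 3 counts over the group. Libraries of a group were compared before they were averaged. Their counts differed far beyond sampling noise, with chi-square over degrees of freedom of 282.5 for the WT-named pair and 467.6 for the KO-named pair, and each was kept as a replicate.

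The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling and the filterByExpr filter, which left 8753 genes, and with Benjamini-Hochberg adjustment at 0.05. CPM values are scaled by the TMM factors, and the standard error (SE) of a log2 fold change is its size divided by the square root of the test's F. Alternatives used DESeq2 1.42.0 and limma-voom (limma 3.58.1). Of 31 gene lists fixed before the data were examined, the 27 with at least 5 tested members were tested 2-sided with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. The lists covered mTORC1 and mTORC2 components, ILC2 identity, ILC2 cytokines and effectors, PPARgamma and its lipid targets, metabolic pathways, ribosome and growth programs, stress and interferon responses, receptors, and markers of other cell types. Ribosomal protein genes were taken by symbol. They have many processed pseudogenes that share their sequence, so their counts are uncertain where the counting could split reads.

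Genes were named by a rule also fixed before the data were examined. It names Rptor, Pparg, Il5, Il13, Gata3, Il1rl1, Klrg1, Areg and Cd36 always, the 10 higher and 10 lower genes with the largest change among those past the adjusted p of 0.05 with non-overlapping libraries and a mean of at least 4 CPM, leaving out predicted genes, pseudogenes and receptor segments, and up to 4 passing members of each list, or its 2 highest expressed members where none passes. No gene met the second part. Other genes are said to be chosen after their values were seen. These are the 5 with the largest change in each direction among the DESeq2 calls, under the same conditions of overlap and level, the 5 with the smallest unadjusted p in each direction at a mean of at least 100 CPM outside the ribosomal proteins, 15 further genes and, among the closing observations, members of a second mast cell list and of the marker lists. 1 gene that the rule names is not reported here.

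The tests were run on simulated counts drawn from the mean of each of 8753 genes and the size of each library, with 200 changed genes and the ribosomal list raised 2-fold. With the spread estimated from these libraries (common dispersion 1.01), the edgeR test called 4 of 100 genes changed 4-fold and 32 of 100 changed 16-fold, with 2 calls among 8469 unchanged genes. DESeq2 called 9 and 55 of them, with 151 calls among the unchanged genes. With a dispersion of 0.05 each tool called all 100 genes at both sizes, with 14 calls among the unchanged genes. Camera found the raised list at both spreads (adjusted p = 8.29e-06 and 5.13e-28) and no other list. Each gene was drawn independently, whereas the real ribosomal list had an estimated inter-gene correlation of 0.508. The simulation therefore cannot show how reliable camera at the preset correlation is for that list.

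The alternatives fixed beforehand were DESeq2, limma-voom, RLE size factors, library size alone, no filter, a filter of at least 5 CPM in 2 libraries, the replicate number as a block, and each library left out. Those added after seeing the data were robust quasi-likelihood fitting, the likelihood ratio test, a filter of at least 50 CPM on the mean, and the DESeq2 count with each library left out or with all libraries thinned to the smallest total.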

Results

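Transcript levels were measured in 4 RNA-seq libraries from group 2 innate lymphoid cells (ILC2) sorted from mouse adipose tissue. ILC2 are tissue-resident lymphocytes without rearranged antigen receptors that secrete type 2 cytokines such as interleukin-5 and interleukin-13. The mice carried a Cre recombinase at the Il5 locus, and in the knockout this deletes floxed alleles of Rptor, which encodes Raptor, the defining subunit of the kinase complex mTORC1. By library name there were 2 WT libraries, with 18151495 and 17868383 counts, and 2 KO libraries, with 15258779 and 18856226 counts. The titles of all 4 samples give the opposite genotype, so the groups are called WT-named and KO-named, and a negative log2 fold change means a lower level in the KO-named libraries. The comparison asks which transcripts differ in adipose ILC2 when mTORC1 is lost.

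Rptor (Entrez 74370, chromosome 11, 119602905 to 119899591, mm10) did not separate the groups. Its level was 14.5 and 76.8 CPM in WT replicates 1 and 3, and 0.971 and 33.9 CPM in KO replicates 1 and 3. The log2 fold change was −1.39 (SE 1.80), with an edgeR adjusted p of 0.906. It was 0.39 when WT replicate 3 was left out and between −5.58 and −0.43 when any other library was. The gene therefore did not settle which of the labels is right, and the counts do not show whether transcripts lacked the floxed part.

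The KO-named libraries held more transcripts of cytosolic ribosomal proteins, the protein components of the translating ribosome. These made up 13.6% ± 3.17 of counts (SD, n = 2) against 7.83% ± 0.20 in the WT-named libraries (SD, n = 2). The ILC2 identity genes Gata3, Il1rl1 and Klrg1 and the effector gene Areg were present in every library. Mast cell transcripts were abundant there as well, so the cells that gave these transcripts are not settled. Gata3, the transcription factor that specifies type 2 lymphocytes, Il1rl1, the receptor for interleukin-33, Klrg1, an inhibitory receptor, and Areg, an epidermal growth factor receptor ligand, differed between the groups by less than 1 SE. Pparg, the fatty acid-sensing nuclear receptor of the study's title, averaged 87.1 CPM ± 11.6 in the WT-named and 39.4 CPM ± 6.79 in the KO-named libraries (SD, n = 2 each), and Il5 averaged 431.6 CPM ± 156.5 and 131.9 CPM ± 63.9, but neither passed the test.

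**Figure D1:**
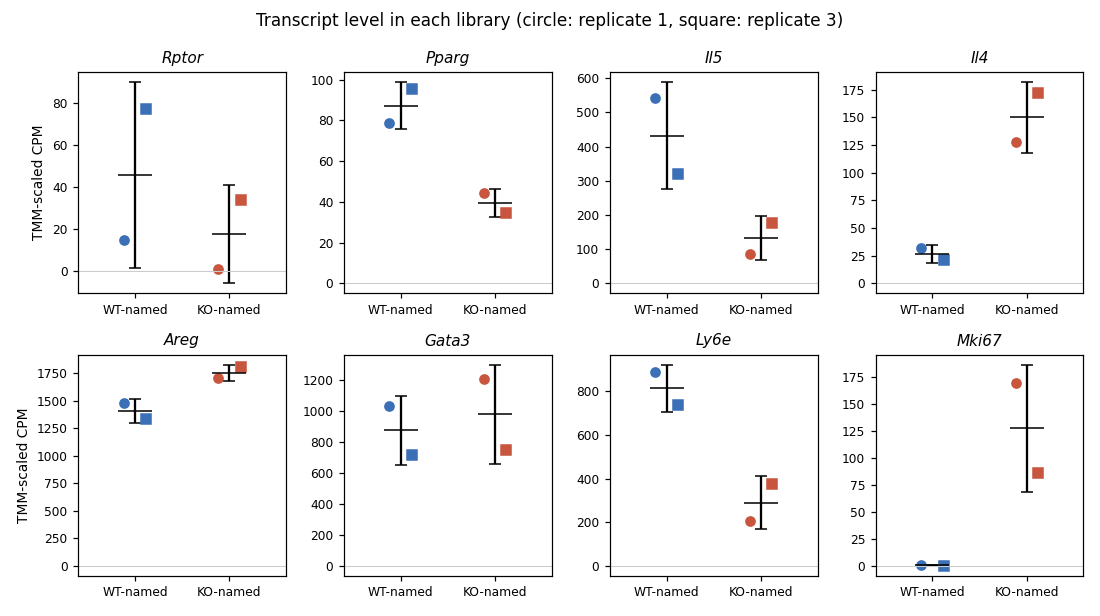
TMM-scaled CPM (y axis, linear, a separate scale per gene) of 8 genes in the WT-named and KO-named libraries. Points are single libraries, and bars are the mean and SD of 2 libraries. Pparg, Il5 and Ly6e lie lower and Il4, Areg and Mki67 higher in both KO-named libraries, while Rptor and Gata3 overlap, and none passed the edgeR test with the 4 libraries and no block.

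No gene of 8753 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.433. At an unadjusted p under 0.05 there were 859 genes, 304 higher and 555 lower in the KO-named libraries, where 437.6 would be expected by chance. With library size alone as the scaling the split was 160 higher and 685 lower. DESeq2 called 952 genes, 250 higher and 702 lower, limma-voom 201 and edgeR's likelihood ratio test 90. With the replicate number as a block edgeR's quasi-likelihood test called 25, although the WT and KO libraries share only their numbers. The genes called by DESeq2 numbered 694, 415, 987 and 1679 without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 3. Of the DESeq2 calls, 734 (77.1%) had 10 or fewer reads in every library of one group. Fewer genes reached 100 reads in KO replicates 1 and 3 (5398 and 6134) than in WT replicates 1 and 3 (7338 and 6585). Libraries of the same group were far apart, with a correlation of log CPM across genes of 0.714 in the WT-named and 0.635 in the KO-named pair. Across the groups it lay between 0.585 and 0.659, and the value of WT replicate 1 with KO replicate 3, 0.659, was above that of the KO-named pair. Leaving out WT replicate 1, WT replicate 3 or KO replicate 3 gave 7, 4 and 5 edgeR calls, and leaving out KO replicate 1 gave 0.

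Among the genes named beforehand, Pparg (Entrez 19016, chromosome 6, 115360879 to 115490404) had a log2 fold change of −1.14 (SE 0.98, edgeR adjusted p = 0.837). Il5 (Entrez 16191, chromosome 11, 53720794 to 53725103), whose product sustains eosinophils, had −1.71 (SE 0.56, edgeR adjusted p = 0.433), and −2.32 without KO replicate 3. The log2 fold change of Gata3 was 0.16 (SE 0.40), of Il1rl1 0.05 (SE 0.35), of Klrg1 0.40 (SE 0.42) and of Areg 0.32 (SE 0.32). With library size alone Gata3 was at −0.19, Il1rl1 at −0.29 and Areg at −0.02. Il13 was scarce, at 14.1 CPM ± 7.43 in the WT-named and 7.09 CPM ± 7.39 in the KO-named libraries (SD, n = 2 each). Its log2 fold change of −0.98 became −0.32, −0.18 and −2.91 without WT replicate 1, KO replicate 1 and KO replicate 3. Cd36 (Entrez 12491, chromosome 5, 17781690 to 17888959), a fatty acid transporter and PPARgamma target, had 1.75 and 53.9 CPM in WT replicates 1 and 3 and no read in either KO-named library. Its pooled level was at least 262-fold lower in the KO-named libraries, against the floor of 3 counts over the group, but that bound rested on WT replicate 3 and was 17.7-fold without it. It was 547-fold, 147-fold and 115-fold without WT replicate 1, KO replicate 1 and KO replicate 3. Its adjusted p was 0.433 by edgeR and 8.31e-05 by DESeq2.

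Cytosolic ribosomal proteins were the 1 list of 27 that passed camera. Their median log2 fold change was 1.13 (quartiles 0.91 and 1.33, 84 genes tested), with a camera adjusted p of 4.76e-13. With an estimated inter-gene correlation the adjusted p was 0.757, and by fry it was 0.223. Over all genes tested 0 members passed edgeR with the 4 libraries and no block, and 54 passed when adjusted over the list alone, all of them higher in the KO-named libraries. Over all genes limma-voom called 18 of them, and Rps27 passed edgeR without WT replicate 3 (adjusted p = 0.0247). In 77 of the 84 both KO-named libraries lay above both WT-named ones (91.7%), where chance gives 16.7% in that direction for a single gene and 1556 of all 8753 tested genes (17.8%) did so. The members varied together (estimated correlation 0.508), so they do not count as independent tests. With 2 libraries per group the smallest exact permutation p is 0.333. Rps27, the highest expressed together with Rpl35, averaged 3100 CPM ± 1127 in the WT-named and 8499 CPM ± 3188 in the KO-named libraries (SD, n = 2 each), a log2 fold change of 1.46 (SE 0.38). For Rpl35 it was 1.34 (SE 0.31). Reads of these genes can be shared with pseudogenes.

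**Figure D2:**
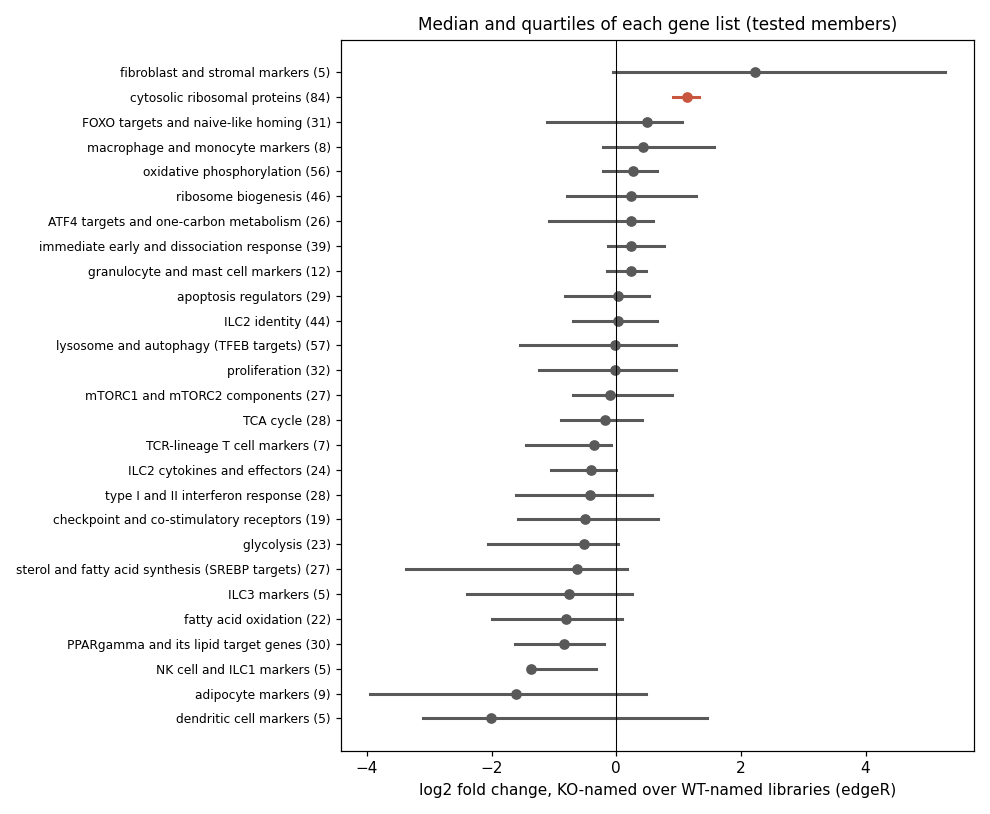
Median (point) and quartiles (bar) of the edgeR log2 fold change, KO-named over WT-named libraries (x axis), of the tested members of the 27 gene lists, with the number of tested members in brackets. The ribosomal proteins, in red, have a median of 1.13 and are the 1 list past the camera test at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.757).

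For the other 26 tested lists the camera adjusted p lay between 0.426 and 0.918. By fry no list passed in 1 direction and 10 passed for changes in either direction. The 10 were ILC2 identity, cytokines and effectors, glycolysis, ATF4 targets, proliferation, lysosome and autophagy, interferon response, T cell, ILC3 and dendritic cell genes. With the 4 libraries and no block no member of any list passed edgeR over all genes. With 1 library left out the fold of 38 of the 95 genes followed moved by over 1.5 times, and 17 of these changed sign. The median of all tested genes was 0.05 with TMM, 0.13 with RLE factors and −0.28 with library size alone, and the medians of 11 lists changed sign with the scaling. These were ILC2 identity, oxidative phosphorylation, ATF4 targets, ribosome biogenesis, proliferation, lysosome and autophagy, apoptosis, immediate early, B cell, granulocyte and mast cell, and erythroid genes.

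Of the lists on mTORC1 and ILC2 function, mTORC1 and mTORC2 components had 27 tested members and a median log2 fold change of −0.11. Their highest expressed members were Rheb, a small GTPase, at 0.69 (SE 0.49), and Rps6kb1, the S6 kinase, at −0.50 (SE 1.07). ILC2 identity genes had a median of 0.02 over 44, with Rora at 0.00 (SE 0.32) and Id2 at −0.22 (SE 0.36), both transcription factors of the lineage. For cytokines and effectors it was −0.41 over 24, with 18 of 24 members below 0. Csf2, the growth factor GM-CSF, had −0.76 (SE 0.35) and Ctla2a −0.18 (SE 0.31). Il4, chosen after its values were seen, went the other way from Il5, at 26.4 CPM ± 7.72 in the WT-named and 149.9 CPM ± 31.9 in the KO-named libraries (SD, n = 2 each, edgeR adjusted p = 0.433). Checkpoint and co-stimulatory receptors had a median of −0.51 over 19, with Cd69, an early activation antigen, at −0.87 (SE 0.49) and Cd200r1, an inhibitory receptor, at 0.79 (SE 0.47). Without WT replicate 3 Cd69 was at −0.11 and Cd200r1 at 1.51, and without KO replicate 3 Cd69 was at −1.47.

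Lists of lipid and central metabolism had medians below 0 with the exception of oxidative phosphorylation. None passed camera, or fry in 1 direction, with all 4 libraries. Glycolysis passed fry for changes in either direction (adjusted p = 0.0147). PPARgamma and its lipid targets had a median log2 fold change of −0.84 over 30 genes, 25 of them below 0. Hilpda, a lipid droplet protein, had −0.17 (SE 0.43) and Dgat1, which makes triglyceride, −0.97 (SE 0.43). The camera adjusted p was 0.426 and 0.757 with an estimated correlation. Fatty acid oxidation had −0.80 over 22, with Etfa at 0.59 (SE 0.83) and Hadhb at −0.79 (SE 0.85). Sterol and fatty acid synthesis had −0.63 over 27, with Elovl5, a fatty acid elongase, at −0.16 (SE 0.31) and Acly, which makes cytosolic acetyl-CoA, at −0.23 (SE 0.82). This list passed camera without KO replicate 1, lower, at an adjusted p of 0.0498, but with all libraries the adjusted p was 0.426, and 0.757 with an estimated correlation. Glycolysis had −0.52 over 23, with Hif1a at 0.11 (SE 0.43) and Ldha, lactate dehydrogenase A, at −1.27 (SE 0.57), which was −0.65 without KO replicate 1 and −2.38 without KO replicate 3. The TCA cycle had −0.18 over 28, with Glud1, glutamate dehydrogenase, at −0.80 (SE 0.54). Oxidative phosphorylation had 0.27 over 56, with Atp5l at 0.41 (SE 0.42) and Cox6c at 0.78 (SE 0.43).

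Of the growth and stress lists, ribosome biogenesis had a median log2 fold change of 0.23 over 46 genes, with the nucleolar proteins Npm1 at 0.96 (SE 0.35) and Ncl at 0.79 (SE 0.49). Proliferation had −0.02 over 32, with Hmgb2 at 0.16 (SE 0.41) and Ccnd2, cyclin D2, at 0.51 (SE 0.47) and at 1.10 without WT replicate 1. Its 1 member that passed when adjusted over the list alone was Mki67, which encodes the cycling cell antigen Ki-67 and was chosen after its values were seen, at 0.63 CPM ± 0.28 in the WT-named and 127.7 CPM ± 58.8 in the KO-named libraries (SD, n = 2 each). ATF4 targets and one-carbon metabolism had a median of 0.23 over 26 whereas camera placed the list lower (adjusted p = 0.637). Slc38a2, an amino acid transporter, had 0.38 (SE 0.34) and Eprs, a transfer RNA synthetase, 0.45 (SE 0.39). Lysosome and autophagy genes had −0.02 over 57, with Map1lc3b at 0.29 (SE 0.43) and Fnip1 at −0.83 (SE 0.60), or −0.23 without WT replicate 3 and −1.79 without KO replicate 1. FOXO targets and homing genes had 0.49 over 31, with Btg1 at −0.09 (SE 0.33) and Il7r at −0.35 (SE 0.34). Apoptosis regulators had 0.03 over 29, with Birc3 at 0.53 (SE 0.38) and Bcl2a1d at −0.83 (SE 0.47), or −1.53 without KO replicate 3. Interferon response genes had −0.42 over 28, with Ly6e at −1.49 (SE 0.45) and Ly6a at −0.02 (SE 0.41). Immediate early and dissociation genes had 0.23 over 39, with Tnfaip3 at −0.05 (SE 0.30) and Nfkbiz at 0.45 (SE 0.30).

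Markers of other cells were present unevenly. Granulocyte and mast cell markers had a median log2 fold change of 0.23 over 12 genes, and the mast cell proteases Cpa3, at 3218 CPM ± 335 in the WT-named and 3651 CPM ± 553 in the KO-named libraries, and Cma1, at 1578 CPM ± 365 and 2607 CPM ± 862 (SD, n = 2 each), were abundant in all 4 libraries. Fibroblast and stromal markers had 2.23 over 5. Gsn was at 599.1 CPM in KO replicate 1 and at most 1.93 CPM elsewhere, and Col1a2 at 225.0 CPM in KO replicate 1 and at most 5.65 CPM elsewhere. Without KO replicate 1 the log2 fold changes were −4.17 for Gsn and −5.46 for Col1a2. Gsn passed when adjusted over the list alone, and it passed edgeR over all genes without WT replicate 1, WT replicate 3 or KO replicate 3 (adjusted p = 3.04e-06, 0.00147 and 0.0235). T cell markers had −0.36 over 7, with Cd3g at −0.36 (SE 0.68) and Ikzf2 at −0.65 (SE 0.70). Cd3e, which passed when adjusted over the list alone and was chosen after its values were seen, had 6.02 and 11.9 CPM in the WT-named libraries and no read in the KO-named ones, at least 88.6-fold lower over the group, a bound of 49.6-fold and 39.0-fold without KO replicates 1 and 3.

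NK cell and ILC1 markers had a median log2 fold change of −1.37 over 5 genes, with Gzmb at −0.12 (SE 0.71) and Klrb1b at −1.37 (SE 1.21), or −0.67 without KO replicate 1 and −2.81 without KO replicate 3. ILC3 markers had −0.76 over 5, with Tnfsf11 at −0.76 (SE 0.43), or −0.089 without WT replicate 3, and Ahr at 1.07 (SE 0.74). Macrophage and monocyte markers had 0.42 over 8, with Ccr2 at 0.18 (SE 0.35) and Fcer1g at 0.03 (SE 0.77). Dendritic cell markers had −2.01 over 5, with Ccr9 at 1.5 (SE 1.56) and Cd83, which passed when adjusted over the list alone, at 42.2 CPM ± 16.5 in the WT-named and 0.325 CPM ± 0.038 in the KO-named libraries (SD, n = 2 each). Adipocyte markers had −1.61 over 9, with Fasn at −4.08 (SE 2.43) and Dgat2 at −3.95 (SE 1.95). Fasn was at 68.3 and 16.3 CPM in WT replicates 1 and 3 and at 5.0 CPM in KO replicate 1, with no read in KO replicate 3, and its log2 fold change was −2.74, −4.75 and −3.07 without WT replicate 1, WT replicate 3 and KO replicate 3. Without KO replicate 1 it was −12.65, a size set by the absence of reads in KO replicate 3. Dgat2 was at −3.14, −3.27 and −5.23 without WT replicate 1, KO replicate 1 and KO replicate 3. In the 4 lists too short for camera, Xbp1 had 0.19 (SE 0.96) among B cell markers, Pecam1 −3.17 (SE 1.29, passing when adjusted over the list alone as its 1 tested member) among endothelial markers, and Hba-a1 −0.88 (SE 0.94) and Itga2b 1.61 (SE 2.04) among erythroid and platelet markers, and no mitochondrially encoded gene was listed. Across the genes named here by the rule the edgeR adjusted p lay between 0.433 and 0.999, the latter for Rora.

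The genes with the largest fold changes among the DESeq2 calls, chosen after their values were seen, were those near absent from a group. Plagl1, a zinc finger transcription factor, was at 98.2 CPM ± 6.43 in the WT-named libraries (SD, n = 2) and had 1 read in the KO-named ones, in KO replicate 3. Phax, Ccne2 and Tm7sf3 had no read in the KO-named libraries and were at least 352-fold, 341-fold and 330-fold lower over the group, bounds that were lowest without KO replicate 3, at 155-fold, 150-fold and 145-fold, and 197-fold, 191-fold and 185-fold without KO replicate 1. Nubp2 also had no read there, but its WT-named levels of 3.17 and 53.5 CPM in replicates 1 and 3 were far apart, and the bound was 32.2-fold without WT replicate 3. In the other direction Inmt, C7, Tmem220, Mettl18 and Ccdc112 averaged 47.5, 95.8, 20.5, 57.0 and 18.2 CPM in the KO-named libraries. In the WT-named ones C7 and Mettl18 had 1 read each, in WT replicate 3, and the others none. Inmt and C7 came almost wholly from KO replicate 1, with 94.8 and 191.4 CPM there, and Ccdc112 and Tmem220 from KO replicate 3, with 36.2 and 39.4 CPM. In edgeR the adjusted p of those among them that were tested was 0.433, and C7 passed without KO replicate 3.

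The authors' deposited table calls 456 genes at a q-value under 0.05, of which 124 have a positive and 332 a negative log2 fold change, and the signs run as KO-named over WT-named. Of these, 367 were among the DESeq2 calls made here and none had the opposite sign. The log2 fold changes of the authors' deposited table and of DESeq2 on these 4 libraries had the same sign in 82.7% of genes and differed by over 1 unit in 27.4%. For Mki67 the authors' deposited table gives 3.73 (q = 0.24) where DESeq2 gave 7.65 here, and for Pparg −0.65 (q = 0.995) where DESeq2 gave −1.16. For Cd83, Fasn and Pecam1 it gives −1.87, −0.49 and −0.74 (q = 0.995 each) where DESeq2 gave −7.00, −4.14 and −3.20. For Plagl1 and Cd3e it gives −11.6 and −8.37 (q = 2.72e-08 and 3.65e-05) where DESeq2 gave −11.6 and −9.54. The deposited q-value for Il4 is 0.019, for Il5 0.435 and for Cd36 0.00215. DESeq2 here gave adjusted p = 0.261, 0.674 and 8.31e-05 for them, so the deposited call of Il4 was not reached. Nor was that of Bcl2a1b, with a deposited q-value of 0.0355 and a DESeq2 adjusted p of 0.418 here. Which libraries entered the deposited comparison is not stated in the sources used here.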

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

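The likelihood ratio test, robust fitting, the filter at 50 CPM and the recounts with DESeq2 were chosen after seeing the data. The edgeR count of 0 genes also held with RLE factors, library size alone, no filter, the filter of 5 CPM in 2 libraries, robust fitting and the filter at 50 CPM, but DESeq2 called 952 genes, limma-voom 201 and the likelihood ratio test 90, and leaving out a library gave 0 (KO replicate 1) to 7 (WT replicate 1). The cause was not tested. The WT and KO libraries share only their numbers, and the deviations of the libraries numbered 1 from their group means had a correlation of −0.007 across genes, so they were not treated as pairs. With the replicate number as a block edgeR called 25 genes, 23 higher and 2 lower, 12 of them ribosomal proteins, including Rps27 (adjusted p = 0.000451) and Rpl35 (0.0018), and Tpt1 (0.000313), Lilr4b (0.000402), Ivns1abp (0.00128), Plagl1 (0.00156), Lilrb4a (0.00257), Mki67 (0.00465) and Uhrf2 (0.0392) passed as well. The genes called by DESeq2 numbered 415 to 1679 with a library left out (694 without WT replicate 1, 415 without WT replicate 3, 987 without KO replicate 1, 1679 without KO replicate 3) and 859 after thinning. Where leaving out replicate 2 of a group was planned, the library whose column is numbered 3 was left out, which could be tied only to its group. The planned pseudocounts apply to FPKM values and were not run, since counts were used. The lists past camera were 1 under each alternative, or 2 without KO replicate 1 (1 to 2 with a library left out), but 0 with an estimated correlation and 0 by fry. The median of the ribosomal list was 1.13 with an adjusted p of 0.757 for the estimated correlation, which was 0.508 in place of 0.01, and 0.223 for fry, which tests the list against no change and not against other genes and whose difference was not traced to a cause, and 0.81 to 1.35 under the other alternatives with an adjusted p of at most 3.27e-05. Of 95 genes followed under 11 alternatives, 63 kept their direction in all. In 1040 such results 49 went past the threshold, 19 of them with limma-voom, 15 with DESeq2 and 11 with the block, and 73 reversed. The cause of these reversals was not tested. With library size alone the log2 fold change was −0.19 for Gata3, −0.29 for Il1rl1, −0.0167 for Areg, −0.19 for Hif1a, −0.16 for Hmgb2, −0.0206 for Map1lc3b, −0.19 for Xbp1, −0.14 for Ccr2, −0.32 for Fcer1g, −0.16 for Cpa3, −0.035 for Hdc and −0.30 for Mcpt4. With RLE factors it was 0.0701 for Rora, 0.0620 for Ly6a, 0.0188 for Tnfaip3 and 0.0558 for Tpsb2. With limma-voom it was −0.042 for Il1rl1, −0.0837 for Fcer1g, −1.59 for Itga2b, 0.23 for Tpsb2 and −0.0685 for Mcpt4. Without a filter it was −0.0648 for Il1rl1, −0.0327 for Fcer1g and −0.0711 for Mcpt4, and with the filter of 5 CPM in 2 libraries −0.0098 for Fcer1g. With the replicate block it was −0.0065 for Il1rl1, −0.14 for Fcer1g, −1.46 for Itga2b, 0.30 for Tpsb2 and −0.0214 for Mcpt4. With 1 library left out the ranges were −5.58 to 0.39 for Rptor, −0.21 to 0.46 for Gata3, −0.39 to 0.37 for Il1rl1, −0.13 to 1.19 for Rheb, −3.16 to 1.07 for Rps6kb1, −0.26 to 0.29 for Rora, −0.59 to 0.31 for Id2, −0.88 to 0.32 for Hilpda, −0.28 to 0.60 for Hif1a, −1.84 to 0.50 for Acly, −0.66 to 1.25 for Etfa, −1.37 to 0.22 for Hadhb, −0.28 to 0.58 for Hmgb2, −0.41 to 0.37 for Btg1, −0.12 to 0.14 for Ly6a, −0.25 to 0.22 for Tnfaip3, −0.80 to 0.39 for Cd3g, −1.20 to 0.24 for Ikzf2, −0.26 to 0.97 for Xbp1, −0.48 to 0.50 for Gzmb, −0.071 to 0.40 for Ccr2, −0.98 to 0.63 for Fcer1g, −4.17 to 9.38 for Gsn, −5.46 to 9.34 for Col1a2, −1.80 to 1.06 for Hba-a1, −5.88 to 2.60 for Itga2b, −0.13 to 0.73 for Hdc, −0.71 to 1.39 for Tpsb2 and −0.48 to 0.42 for Mcpt4. A group left with 1 library is assumed to vary like the other. Differences within the floor of 3 counts per library were not detectable at this depth.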

Other observations

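Apart from Cpa3, Cma1, Gsn and Col1a2, the genes named among these observations were chosen after their values were seen, and the tests of scaling, of tissue background and of other splits were chosen only after their results were seen.

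Outside the ribosomal proteins, the genes with a mean of at least 100 CPM and the smallest unadjusted p included the paired receptors Lilr4b and Lilrb4a, which are neighbours on chromosome 10 and near-identical, so that their counts are uncertain. Lilr4b averaged 815.5 CPM ± 34.3 in the WT-named and 2933 CPM ± 877 in the KO-named libraries, and Lilrb4a 1510 CPM ± 208 and 4366 CPM ± 1410 (SD, n = 2 each). Tpt1, the translationally controlled tumour protein, averaged 7488 CPM ± 1468 and 18800 CPM ± 4.56, Ivns1abp 1141 CPM ± 316 and 3488 CPM ± 327, and Senp7, a SUMO protease, 47.1 CPM ± 9.63 and 317.4 CPM ± 18.4. Further genes in that direction were Hes1, a Notch target, at 107.1 CPM ± 13.4 and 470.9 CPM ± 107.9, and Myc at 102.5 CPM ± 23.7 and 313.6 CPM ± 169.5. In the other direction stood the survival factor Bcl2a1b (439.6 CPM ± 154.5 and 97.1 CPM ± 29.8), Rgcc (808.2 CPM ± 169.2 and 252.9 CPM ± 46.1) and Uhrf2 (579.6 CPM ± 0.17 and 146.1 CPM ± 91.4). Cd274, which encodes PD-L1, averaged 107.0 CPM ± 12 and 6.52 CPM ± 2.72 and the sestrin Sesn3 3.33 CPM ± 1.59 and 50.4 CPM ± 32.0. None passed edgeR's adjusted p over all genes with the 4 libraries and no block, whereas Tpt1, Ivns1abp, Lilr4b and Lilrb4a passed limma-voom (adjusted p = 0.00101, 0.0129, 0.0148 and 0.017) and Cd274 and Sesn3 DESeq2 (adjusted p = 0.0208 and 0.0337). The log2 fold change of Myc was 1.61, or 0.93 without KO replicate 1. For Uhrf2 it was −1.99, or −2.84 without KO replicate 3. For Sesn3 it was 3.92, or 4.61 without WT replicate 3 and 3.04 without KO replicate 3.

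Some genes were present in both WT-named libraries and near absent from both KO-named ones: 241 genes had 100 or more reads in each of the former and 10 or fewer in each of the latter, against 16 in the reverse direction and at most 87 for either other split of the 4 libraries into pairs. Fewer genes reached 100 reads in KO replicates 1 and 3 (5398 and 6134) than in WT replicates 1 and 3 (7338 and 6585). That difference has the same direction as 241 against 16. Genes at 0 reads went the other way, with 115 and 273 in KO replicates 1 and 3 and 686 and 647 in WT replicates 1 and 3. Detection was thus lower in the KO-named libraries at 100 reads, and not in the number of genes without reads. Lower detection at 100 reads in both KO-named libraries could not be told apart from loss of particular genes. Sequencing depth is argued against by the totals, since KO replicate 3 had the largest, 18856226, and these genes were near absent there too. Thinning all libraries to the smallest total left 0.929 of the number, but the totals were too close for it to fall much. Loss independent in each library, at rates set by WT-named abundance alone, is argued against as well. Genes lost from both KO-named libraries were 2.05 times as many as the product of the loss rates within 10 bins of abundance gives (95% bootstrap interval 1.89 to 2.22). The ratio cannot exclude independent loss at rates that differ between genes of similar abundance, which would raise it too. A shared proneness of some transcripts to be lost in library making stays open. Of 556 genes abundant in WT replicate 1 and near absent from WT replicate 3, a share of 0.252 was also near absent from both KO-named libraries (95% interval 0.216 to 0.290). The share was 0.053 among the other genes abundant in WT replicate 1, which were not matched on abundance, so a difference in level may enter. Shared proneness may account for part of the pattern, and the genotype, untested and with contradictory labels, stays open too. DESeq2 called 952 genes for the real split and at most 350 for another, and with 3 splits a share under 0.05 cannot be reached.

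The higher level of ribosomal protein transcripts in the KO-named libraries was weighed against 3 technical explanations. The choice of scaling is argued against as the whole cause, since the median log2 fold change of the list was at least 0.81 and its lower quartile at least 0.58 under 4 scalings that moved the median of all tested genes over a range of 0.41, and the list held 7.68% and 7.97% of counts in the WT-named against 11.4% and 15.9% in the KO-named libraries. Genes matched on transcript length and mean expression had a median log2 fold change of 0.25, so short or abundant transcripts may carry part of the shift, but the list lay 0.757 above them at the 2.5 percentile of 10000 draws. The length was that of the longest annotated transcript, with a median of 1076 for the list and 1183 for its matches. The transcripts expressed may be shorter, so a preference for short ones stays open. No single library carried it, since the lowest median with 1 library left out was 0.754 of the full value. Reads shared with pseudogenes and the genotype were not tested, and the list's call was lost with an estimated correlation (adjusted p = 0.757), so the shift remains a hypothesis about these 4 libraries.

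Mast cell transcripts were abundant in all 4 libraries, and the sorting gate is not given in the sources used here. Beside Cpa3 and Cma1 the means over the 4 libraries were 1214 CPM for Kit, 500.7 for Hdc, 389.3 for Tpsb2, 248.0 for Mcpt4 and 218.6 for Fcer1a, and Kit is also on the ILC2 list. In a second list of 37 mast cell genes, of which 3 stand on other lists and several are expressed by most leukocytes, a share of 0.862 of the 29 measured ones had a mean of 10 CPM or more, including Rab27b at 961.1, Mrgprb1 at 394.1, Mrgprb2 at 196.3 and Slc18a2 at 164.5 CPM. As 0.603 of all listed genes reached that level too, the test was too easily passed to decide, and mast cells among the sorted cells remain a candidate explanation. Of 123 markers of B cells, fibroblasts, endothelium, adipocytes and dendritic cells, 38 were measured, with a median of 2.31 CPM. That was 0.0336 of the median of the second mast cell list (95% bootstrap interval 0.00412 to 0.183). The ratio cannot decide on a general background of tissue RNA, since several genes of the second list are not particular to mast cells. It shows only that these markers were scarcer than that list. The types differed, with medians of 20.8 CPM for fibroblasts, 11.1 for dendritic cells, 3.18 for adipocytes, 0.130 for endothelium and 0.0956 for B cells. Of the 38 markers, 14 reached 10 CPM, up to 150.4 for Gsn. The fibroblast markers included Gsn, Col1a2 and Col6a3, which came almost wholly from KO replicate 1, and Thy1, which is also on the ILC2 list.

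Col6a3, a stromal collagen, was at 117.8 CPM in KO replicate 1 and at most 0.322 CPM in the other libraries, the same distribution as Gsn and Col1a2. Rps24 and Rpl5 averaged 1682 CPM ± 370 and 2350 CPM ± 563 in the WT-named and 5055 CPM ± 37.5 and 6301 CPM ± 1108 in the KO-named libraries (SD, n = 2 each).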
